A study of Rattus norvegicus with 6 samples.

How the data were processed

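Total liver RNA of 6 male Sprague-Dawley rats was labelled with Cy3 and hybridised to Agilent 1-colour arrays, per the labels' protocols. The deposited scanner files give spot intensity for each array from Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.1.1 per the file headers. The processed signal is an intensity after background subtraction and spatial detrending, per the file headers, and is not normalized between arrays. The authors' deposited value table holds the same intensity divided by 1 factor per array, which was found by setting it against the scanner values. The factor was within 0.0629% of constant on every array and close to the array's 75th percentile, so the deposited values are linear, not centred per gene, and runs in the same direction. Column medians of the table were 0.0984, 0.101 and 0.102 for corn oil replicates 1 to 3 and 0.0955, 0.0941 and 0.096 for phenolphthalein replicates 1 to 3.

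Groups and replicate numbers were taken from the labels, which name 3 animals per treatment, and 1 array stands for 1 animal. The number of arrays limits the precision. The 75th percentile of the signal was 622, 636 and 595 on the corn oil arrays and 578, 562 and 551 on the phenolphthalein arrays. No spot was saturated, and 4 to 14 spots per array carried an outlier mark. Corn oil arrays were on slide 1 and scan 1 and phenolphthalein arrays on slide 2 and scan 2. Pearson correlations between arrays, over genes, were 0.989 to 0.99 within corn oil, 0.982 to 0.989 within phenolphthalein and 0.979 to 0.989 between groups, and genes are not independent replicates.

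The main values were log2 of the processed signal minus each array's 75th percentile of it over the 61657 spots other than controls. Outlier-marked spots were set missing. Probes well above background on at least 3 of the 6 arrays, whatever the group, were kept. Each probe had 1 spot. Probes were named by matching their unversioned accession to a RefSeq table of assembly GRCr8, which is used for names alone, since the array design was annotated on another build. Of the probes, 27460 matched 1 gene, 0 matched several and 34197 matched none and stayed out of the main test. For 5739 genes with over 1 probe past the filter, the probe with the highest mean over all 6 arrays stood for the gene. The 15284 genes on the array became 11434 tested genes. For a probe not well above background on any array of 1 group, the fold is given as a lower bound, the bright group's mean over its arrays against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

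Genes were tested in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with lmFit and eBayes, phenolphthalein minus corn oil, and Benjamini-Hochberg adjustment at 0.05, with a log2 fold change of 1 as the size threshold. The 22 process lists and 12 cell type lists were fixed before the data were examined, and the other choices of the main test too. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists, and with camera at an estimated correlation and with fry as alternatives. Genes with a missing spot, 8 in number, stayed out of the list tests. Counts per list are given over all genes and adjusted over the list alone. With an estimated correlation 0 of 34 lists passed.

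The genes named were fixed by a rule. They were the 12 highest and 12 lowest log2 fold changes past the adjusted threshold whose groups did not overlap, of which there were 6 and 1. To these came the 3 members with the smallest p of every list, and Cyp2b1, Cyp3a23-3a1, Cyp1a1, Cyp1a2, Cyp4a1, Cyp7a1, Nqo1, Ugt1a1, Abcc2, Abcc3, Cdkn1a, Mki67, Gstp1, Afp, Cyp2c11 and Alb. Some genes that the rule takes are not reported here. Apoa4 and Mvk were chosen after their values were seen, as examples of the line of dim spots.

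Alternatives were normexp with an offset of 50, quantile normalization, a median shift, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, an intensity trend with a robust prior, marked spots kept, the authors' deposited values, each array left out, and the replicate number as a block. Normexp ran on the median spot signal, since the mean spot signal named in the plan is not used here. Masking of array columns with at least 5% of bright spots over 2 log2 units low, and testing accessions without a gene name together with the named genes, were added after the data were seen.

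The gene and list tests were tested on simulated data made from the real means and SDs of 11426 genes, with 200 changed genes in each of 20 simulations. Of 2-fold changes 66.1% were recovered, of 4-fold changes 89.9% and of 8-fold changes 95.7%, and 5.16%, 5.12% and 5.2% of calls were false. These shares hold for 200 changed genes. The real comparison called 7, where the adjustment asks for a smaller p, so recovery in the real data may be lower. With no change there were 0.1 calls per simulation on average. Over 20 simulations without change, camera called 1 list in all, in simulated data whose genes were independent.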

Results

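Liver RNA of 6 male Sprague-Dawley rats was hybridised to 1-colour oligonucleotide arrays, 1 array per animal. The labels put 3 animals in a corn oil group, the vehicle, and 3 in a group given phenolphthalein, a pH indicator dye once sold as a laxative, at 1000 mg per kg per day. The labels disagree on the length of treatment, since the design text speaks of 28 days and the treatment protocol of 9 weeks. Rats were 5 weeks old when bought. Each array had 61657 probes other than controls, and the share well above background was 62.1% to 65.1% per array. Of these probes, 27460 matched 1 gene, and 11434 genes were tested. All corn oil arrays lay on slide 1 and all phenolphthalein arrays on slide 2, which were scanned separately, so slide, scan and treatment cannot be told apart in any comparison given here.

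The comparison asked which liver transcripts differed between animals given phenolphthalein and animals given corn oil. The clearest difference was a rise of Cyp2b genes, which code for cytochrome P450 enzymes and of which Cyp2b1 and Cyp2b2 are the phenobarbital-inducible forms of rat liver. Cyp2b1 was 12.2-fold higher with phenolphthalein, from a log2 signal of 4.46 ± 0.08 to 8.07 ± 0.39 (SD, n = 3 per group, relative to the array's 75th percentile). Cyp2b2 was 11.2-fold higher, Cyp2b12 10.3-fold, Cyp2b15 7.19-fold and Cyp2b21 3.58-fold. Ugt2b1, a UDP-glucuronosyltransferase that conjugates drugs and steroids with glucuronic acid, was 6.46-fold higher, from 4.77 ± 0.36 to 7.46 ± 0.14 (SD, n = 3 per group).

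In limma's moderated test with Benjamini-Hochberg adjustment over the 11434 genes, these 6 genes were higher and 1 gene was lower at an adjusted p under 0.05. The log2 fold changes were 3.61 ± 0.20 (SE) for Cyp2b1, 3.49 ± 0.21 for Cyp2b2, 3.36 ± 0.21 for Cyp2b12 and 2.85 ± 0.17 for Cyp2b15, each with a limma adjusted p of 0.0108. They were 1.84 ± 0.13 (SE) for Cyp2b21, with a limma adjusted p of 0.0157, and 2.69 ± 0.19 for Ugt2b1, with 0.0176. All 6 changed at least 2-fold, and the 3 phenolphthalein arrays lay above the 3 corn oil arrays for each. The gene that fell was Neurod6, a neuronal transcription factor, with a log2 fold change of -0.95 ± 0.08 (SE) and a limma adjusted p of 0.0351. Its probe was dim, at -2.88 ± 0.09 in corn oil and -3.83 ± 0.04 with phenolphthalein (SD, n = 3 per group), and its second probe was well above background on 0 of 6 arrays. Neurod6 passed in 6 of 18 alternative settings, over which its log2 fold change ran from -0.99 to -0.41. No gene fell at least 2-fold at that threshold in limma, against 65 with an unadjusted p under 0.05. Over all genes, 1746 had an unadjusted p under 0.05 (819 higher and 927 lower), where 572 are expected by chance, and 31 had an adjusted p under 0.1. Quantile normalization gave 7 genes higher and 0 lower. Leaving out corn oil replicate 1, corn oil replicate 3 or phenolphthalein replicate 1 left 0 genes past the threshold, and leaving out corn oil replicate 2 or phenolphthalein replicate 2 left 1, while without phenolphthalein replicate 3 there were 6, of which 5 were the same genes. The log2 fold change of Cyp2b1 stayed between 3.46 and 3.83 in these fits.

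**Figure D1:**
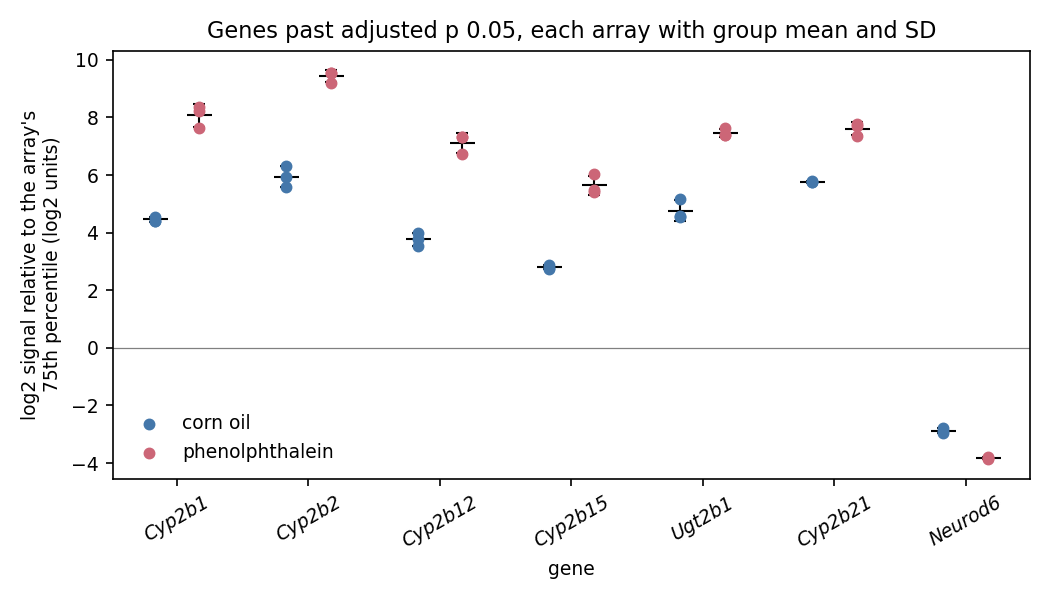
Log2 signal relative to the array's 75th percentile (vertical axis, log2 units) of the 7 genes past the threshold (horizontal axis). Points are single arrays of the corn oil and phenolphthalein groups, and bars give the group mean and SD (n = 3 per group). The phenolphthalein arrays lie above the corn oil arrays for 6 genes and below them for Neurod6.

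The Cyp2b genes are paralogs with closely similar sequences, so the signal of a probe may not belong to 1 of them alone. The 5 probes of Cyp2b2 were 2.55 to 4.52 log2 units higher with phenolphthalein. The second probe of Cyp2b21 was 4.72 log2 units higher, against 1.84 for the tested probe. Of the other probes of Cyp2b15, 1 was not well above background on any of the 3 corn oil arrays and was at least 1.86-fold higher on the phenolphthalein arrays, well above background on 3 of 3. The other read 0.86 on phenolphthalein replicate 2 and -5.00 and -4.26 on replicates 1 and 3, against a corn oil mean of -4.20. The second probe of Cyp2b12 was well above background on 0 of 6 arrays. With the mean of a gene's probes in place of the brightest, Cyp2b15 had a log2 fold change of 2.38 and did not pass.

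The list of CAR and PXR target genes, the genes induced through the nuclear receptors that sense drugs, was higher as a group (limma camera adjusted p = 4.5e-10, and adjusted p = 0.285 with an estimated correlation). Of its 22 measured members, 4 were higher over all genes tested, 0 were lower and 18 did not pass. Adjusted over the list alone, 8 were higher and 0 lower, and the median log2 fold change was 0.57. The members higher over all genes were Cyp2b1, Cyp2b2, Cyp2b15 and Ugt2b1. Cyp3a23-3a1, a main PXR-induced P450, had a log2 fold change of 0.35 ± 0.15 (SE) and Abcc2, a canalicular export pump, one of 0.07 ± 0.13, and neither passed.

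Glucuronidation and sulfation genes were higher as a group (camera adjusted p = 0.00566, and adjusted p = 0.372 with an estimated correlation). Of 24 measured members, Ugt2b1 was higher over all genes and 23 did not pass, and 2 were higher adjusted over the list alone. The median log2 fold change was 0.24, and 0.14 without phenolphthalein replicate 2. The mean was higher for 19 members and lower for 5. All 11 measured UDP-glucuronosyltransferases had a higher mean, while of 8 sulfotransferases 5 had a higher and 3 a lower one. Ugt1a2 and Ugt1a6 moved alike from array to array, so the 11 may not be separate measures. Ugt2b37 had a log2 fold change of 0.71 ± 0.15 (SE), Ugt2b35 one of 0.41 ± 0.12 and Ugt1a1, the bilirubin-conjugating enzyme, one of 0.30 ± 0.17. The 3 sulfotransferases with a lower mean, chosen after their values were seen, were Sult2a1 at -1.03 ± 0.57 (SE), Sult1e1 at -0.75 ± 0.37 and Sult1c2 at -0.35 ± 0.14, and none of them passed. Ugt2b1 is also a member of the CAR and PXR list.

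Interferon response genes were lower as a group with phenolphthalein (camera adjusted p = 4.55e-09, and adjusted p = 0.372 with an estimated correlation). The mean was lower for 24 of 27 measured members and the median log2 fold change was -0.65. All phenolphthalein arrays lay below all corn oil arrays for 16 members, which holds for 10.98% of all tested genes and for 5% by chance. The median deviation of the members from their mean over the 6 arrays was 0.51, 0.05 and 0.18 log2 units on corn oil replicates 1 to 3 and -0.43, -0.17 and -0.31 on phenolphthalein replicates 1 to 3, so corn oil replicate 1 stood highest. Without that array the median log2 fold change was -0.50 and the list still passed (camera adjusted p = 8.73e-08). No member passed over all genes in limma, against 13 with an unadjusted p under 0.05, all lower, and 11 were lower adjusted over the list alone. Cd74, the invariant chain of MHC class II, had a log2 fold change of -0.69 ± 0.11 (SE), the immunoproteasome subunit Psmb8 one of -0.59 ± 0.11 and Oasl2, an interferon-induced gene, one of -1.02 ± 0.20.

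Markers of Kupffer cells and macrophages, the phagocytes of the liver, were lower as a group (camera adjusted p = 4.55e-08, and adjusted p = 0.372 with an estimated correlation). The mean was lower for 13 of 13 measured members, 0 passed over all genes in limma, 11 had an unadjusted p under 0.05 and 11 were lower adjusted over the list alone. The median log2 fold change was -0.63. All phenolphthalein arrays lay below all corn oil arrays for 8 of the 13 members, against the same 10.98% of all tested genes and 5% by chance. The median deviation of the members was 0.52, 0.37 and 0.09 log2 units on corn oil replicates 1 to 3 and -0.50, -0.44 and -0.03 on phenolphthalein replicates 1 to 3, so the third replicates of both groups lay close together. The scavenger receptor Marco had a log2 fold change of -1.45 ± 0.28 (SE), Cd163 one of -0.63 ± 0.15 and Csf1r, the receptor of macrophage colony-stimulating factor, one of -0.51 ± 0.13. Lymphocyte markers were lower as a group (camera adjusted p = 0.000301, and adjusted p = 0.372 with an estimated correlation), with a lower mean in 8 of 8 members and a median of -0.43. None passed over all genes in limma, 4 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. Ptprc, which codes for the leukocyte antigen CD45, had a log2 fold change of -0.59 ± 0.11 (SE), Lck one of -0.50 ± 0.13 and Cd3d one of -0.30 ± 0.10. Over the alternative settings these ran from -0.74 to -0.51, -0.574 to -0.135 and -0.35 to -0.21.

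**Figure D2:**
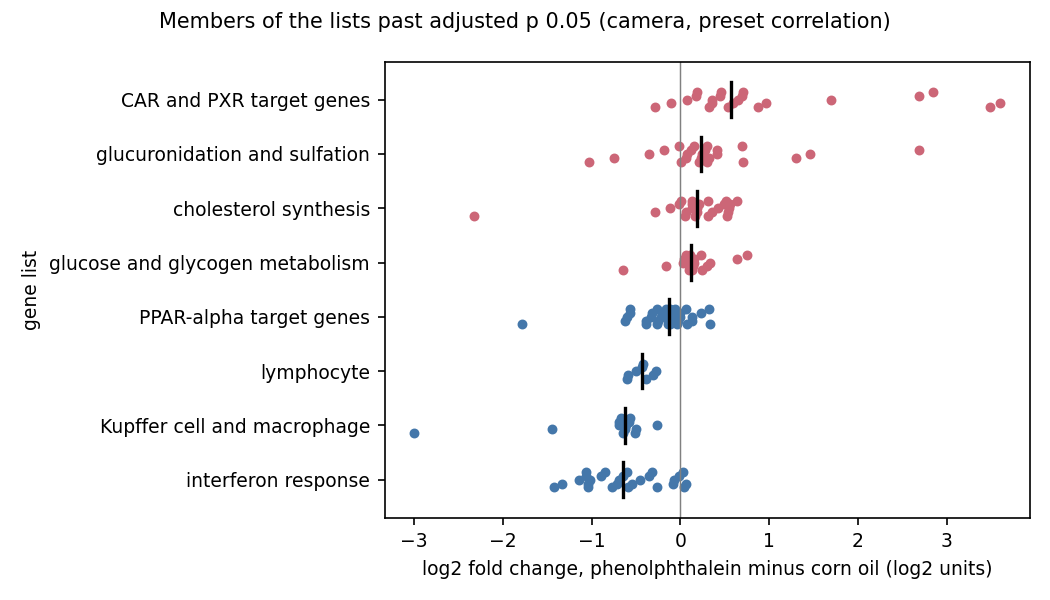
Log2 fold change, phenolphthalein minus corn oil (horizontal axis, log2 units), of each measured member of the 8 lists past the threshold with camera's preset correlation (vertical axis). Points are genes, red for lists called higher and blue for lists called lower, and black lines are medians, which run from -0.65 for interferon response to 0.57 for CAR and PXR target genes.

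Cholesterol synthesis genes were higher as a group (camera adjusted p = 0.0242, and adjusted p = 0.696 with an estimated correlation). The median log2 fold change over 25 members was 0.19, and 0 passed in limma over all genes or over the list alone, against 7 with an unadjusted p under 0.05. Squalene epoxidase, Sqle, had a log2 fold change of 0.64 ± 0.24 (SE), Tm7sf2 one of 0.31 ± 0.10 and Mvd one of -0.28 ± 0.09. Glucose and glycogen genes were higher as a group (camera adjusted p = 0.0365, and adjusted p = 0.372 with an estimated correlation), with a median of 0.12 over 20 members, 0 of them past limma's threshold over all genes or over the list alone and 1 with an unadjusted p under 0.05. The log2 fold change was 0.33 for Insr, the insulin receptor, 0.75 for Pfkfb1 and 0.30 for Gys2, liver glycogen synthase. These ran from 0.26 to 0.42, 0.38 to 0.95 and 0.16 to 0.37 without 1 array. PPAR-alpha target genes, many of them enzymes of fatty acid oxidation, were lower as a group (camera adjusted p = 0.0242, and adjusted p = 0.696 with an estimated correlation). Their median was -0.13 over 36 members, 0 passed in limma over all genes or over the list alone, and 4 had an unadjusted p under 0.05. Ech1 had a log2 fold change of -0.39 ± 0.10 (SE), Cyp4a1 one of -0.62 ± 0.21 and Eci1 one of -0.38 ± 0.14. The cholesterol call was lost under 3 of the 6 fits that leave out an array (without corn oil replicate 1 or 2 or phenolphthalein replicate 2), as was the glucose call, and the PPAR-alpha call was lost without corn oil replicate 1, phenolphthalein replicate 1 or phenolphthalein replicate 2. The cholesterol median was 0.10 without corn oil replicate 2 and 0.11 without phenolphthalein replicate 2, and the PPAR-alpha median was -0.07 without corn oil replicate 1. The cholesterol and glucose calls were also lost with quantile normalization or a median shift, which gave 2 lists higher in place of 4, with 5 and 4 lower. Each list was also set against 10000 random lists of the same mean signal, after the data were seen. Of these, 99.98% had a lower median than cholesterol synthesis, 95.05% than glucose and glycogen and 0% than PPAR-alpha targets. The random medians were 0.04, 0.054 and 0.059, so genes of that brightness shared part of the glucose shift.

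The other 26 lists did not pass with camera, and no member of them passed over all genes in limma. Leaving out 1 array moved the median of 25 of these 26 lists by over 1.5 times or turned its sign, and the sign turned for 9. Among lists of xenobiotic response, AhR target genes had a median log2 fold change of 0.24 (camera adjusted p = 0.0884), with values of 0.47 for Cyp1a2 and 0.79 for Ahr. Cyp1a2 ran from 0.37 to 0.62 and Ahr from 0.485 to 1.23 without 1 array. Cyp1a1 was well above background on 0 of 3 corn oil and 1 of 3 phenolphthalein arrays and was not tested. NRF2 target genes had a median of 0.15 (camera adjusted p = 0.219), which ran from -0.004 to 0.15 without 1 array, with 0.67 for glutathione reductase, Gsr, 0.31 for Tkt, 0.59 for Txnrd1, 0.06 for Nqo1 and 0.52 for the export pump Abcc3, and 1 member was higher adjusted over the list alone. Male-predominant liver genes had a median of 0.18 (camera adjusted p = 0.0912), with 0.54 for Cyp3a2, 0.40 for Cyp2c11 and 0.29 for Mup4, and 2 were higher adjusted over the list alone. Cyp3a2 and Cyp3a18 of this list are also members of the CAR and PXR list, as are Cyp2a1, Cyp2c7 and Cyp3a9 of the female-predominant list. For female-predominant genes the median was -0.60 (camera adjusted p = 0.139), with 0.36 for Cyp2a1 and -1.05 for A1bg. A1bg was well above background on 3 of 3 corn oil and 2 of 3 phenolphthalein arrays. It ran from -1.38 to -0.53 without 1 array and reached -0.155 over its alternatives. Prlr, the prolactin receptor, was well above background on 2 of 3 corn oil and 1 of 3 phenolphthalein arrays, and its log2 fold change of -3.50 ± 1.66 (SE) rests in part on values near background. The female-predominant list passed without phenolphthalein replicate 3, with a median of -0.79, and had one of -0.19 without phenolphthalein replicate 2, with camera adjusted p from 0.0162 to 0.696 over its alternatives. The male-predominant list passed without phenolphthalein replicate 1, with a median of 0.10, and its adjusted p ran from 0.0126 to 0.542.

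Among metabolic lists, bile acid genes had a median of 0.04 and a mean of -0.02 (camera adjusted p = 0.958, direction lower). Their values were -0.50 for Cyp7b1, the 1 member lower adjusted over the list alone, -0.57 for Cyp8b1, 0.19 for Scp2 and -0.82 ± 0.85 (SE) for Cyp7a1, the rate-limiting enzyme of bile acid synthesis. Fatty acid and triglyceride synthesis had a median of 0.08 (camera adjusted p = 0.552), with 0.34 for Acaca, -0.45 for Fads2 and 0.22 for Acly. Amino acid and urea metabolism had a median of 0.12 (camera adjusted p = 0.0622), with 0.84 for Gpt and 0.75 for Tdo2. It passed without corn oil replicate 3 or phenolphthalein replicate 1, with medians of 0.16 and 0.17. Without 1 array the median ran from 0.06 to 0.18, and adjusted p over its alternatives from 0.00312 to 0.696. Iron and haem genes had a median of 0.03 (camera adjusted p = 0.799), with 0.48 for Id1, the 1 member higher adjusted over the list alone, -0.28 for Bmp6 and -0.49 for Hmox1.

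Among lists of stress and growth, cell cycle genes had a median of -0.05 (camera adjusted p = 0.5), with 0.32 for Mcm7, 0.36 for Kif11 and -0.49 for Nusap1, and Mki67 had no probe matched by name. The p53 and DNA damage list had a median of 0.07 (camera adjusted p = 0.654), with -0.26 for Fas, 0.43 for Plk3, 0.46 for Gadd45a and -0.11 for Cdkn1a. Plk3 ran from 0.24 to 0.58 and Gadd45a from 0.25 to 0.64 without 1 array. ER stress genes had a median of -0.13 (camera adjusted p = 0.0784), with -0.47 for Chac1, -0.51 for Ddit3 and -0.29 for Calr. Heat shock genes had a median of -0.06 (camera adjusted p = 0.634), with -0.86 for Hspa1a, -0.34 for Hspb1 and -0.22 for Hsph1. These genes ran from -1.41 to -0.52, -0.61 to -0.18 and -0.42 to -0.10 without 1 array. The acute phase list had a median of 0.14 (camera adjusted p = 0.0756), with 0.46 for Orm1, 0.57 for Stat3 and 0.23 for haptoglobin, Hp. Immediate early genes had a median of -0.10 (camera adjusted p = 0.134), with -0.91 for Dusp1, -0.89 for Egr1 and -0.24 for Nr4a1. The circadian list had a median of -0.07 and a mean of -0.02 (camera adjusted p = 0.958, direction higher), with 0.29 for Cry1, 0.16 for Clock and -0.54 for Per2. Its members moved in opposite directions between arrays, so a median or a test of 1 direction says little about this list. Cry1 ran from 0.16 to 0.43 and Clock from 0.01 to 0.32 without 1 array. Markers of preneoplastic liver foci had a median of 0.11 (camera adjusted p = 0.634), with 0.48 for Afp, 0.43 for Prom1 and -0.13 for Gstp1. Afp ran from 0.32 to 0.69, Prom1 from 0.13 to 0.61 and Gstp1 from -0.23 to -0.04 without 1 array. Without phenolphthalein replicate 1, the ER stress, acute phase and immediate early lists passed, with medians of -0.23, 0.17 and -0.30. The acute phase list also passed without corn oil replicate 3, with 0.14, and the cell cycle list without corn oil replicate 1, with -0.17. Over the 6 fits that leave out 1 array, medians ran from -0.23 to -0.04 for ER stress, 0.07 to 0.17 for the acute phase, -0.30 to 0.02 for immediate early genes and -0.17 to 0.02 for the cell cycle. Over their alternatives, adjusted p ran from 0.0139 to 0.696 for ER stress and for immediate early genes, from 0.0104 to 0.696 for the acute phase and from 0.0137 to 0.96 for the cell cycle.

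Among cell types, hepatocyte markers had a median of 0.04 (camera adjusted p = 0.552), with 0.10 for Apoh, 0.09 for Ttr, 0.08 for Rbp4 and 0.01 for albumin, Alb. Pericentral hepatocyte genes had a median of -0.24 (camera adjusted p = 0.288), with -0.49 for Glul, -0.31 for Slc1a2 and, the other way, 0.47 for Cyp1a2. Periportal genes had a median of 0.10 (camera adjusted p = 0.552), with 0.20 for Gls2, 0.30 for Arg1 and -0.16 for Hsd17b13. Cholangiocyte markers had a median of 0.29 (camera adjusted p = 0.0859), with 0.85 for the chloride channel Cftr, 0.92 for Spp1 and 0.29 for Epcam, and these 3 were higher adjusted over the list alone. The median was -0.12 for stellate cells and fibroblasts (camera adjusted p = 0.0859), with -0.48 for Col1a1, -0.51 for Dcn and -0.26 for Col3a1. It was -0.08 for endothelial cells (camera adjusted p = 0.139), with -0.29 for Cdh5, -0.23 for Tek and -0.17 for Fcgr2b. Neutrophil markers had a median of -0.13 (camera adjusted p = 0.552), with -0.39 for Camp, the 1 member lower adjusted over the list alone, -0.60 for Retnlg and 0.57 for S100a9. Erythroid markers had one of -0.24 (camera adjusted p = 0.219), with -0.38 for Ahsp, -0.57 for Epb42 and -0.42 for Alas2. Adipocyte markers had one of -0.18 (camera adjusted p = 0.487), with -0.26 for Cidec, -0.37 for Fabp4 and -0.11 for Retn, which was well above background on 2 of 3 arrays of each group. Pancreatic acinar markers had a median of 0.02 and a mean of 0.03 (camera adjusted p = 0.815, direction lower), with -0.73 for Cela2a, the 1 member lower adjusted over the list alone and well above background on 2 of 3 phenolphthalein arrays, 0.15 for Cel and 0.66 for Cpb1. Cel ran from 0.07 to 0.29 and Cpb1 from 0.125 to 1.70 without 1 array. The cholangiocyte list passed without corn oil replicate 3, with a median of 0.34, and had one of 0.12 without corn oil replicate 2. The stellate list passed without phenolphthalein replicate 1, with a median of -0.24. Over their alternatives, adjusted p ran from 0.0405 to 0.372 and from 0.00365 to 0.696. Without 1 array, medians ran from -0.24 to -0.12 for stellate, -0.12 to -0.03 for endothelial, -0.28 to 0.08 for neutrophil, -0.35 to -0.06 for erythroid and -0.36 to -0.03 for adipocyte markers, -0.33 to -0.10 for pericentral and 0.04 to 0.16 for periportal genes.

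On phenolphthalein replicate 1, a line of spots read near background. In column 58 of that array, 57 of 60 bright spots in even rows lay over 2 log2 units below the median of the other arrays, against 0 of 56 in odd rows. The tested probe of Apoa4 read -6.62 there and 8.63 to 9.22 on the other 5 arrays, which gave a log2 fold change of -4.95 ± 4.29 (SE) that did not pass. Mvk of the cholesterol list was on the same line, at -7.58 against -0.72 to -0.44 on the other arrays. With columns of this kind treated as missing, a choice made after seeing the data, the 7 genes past the threshold were the same, and 4 lists were higher and 4 lower.

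**Figure D3:**
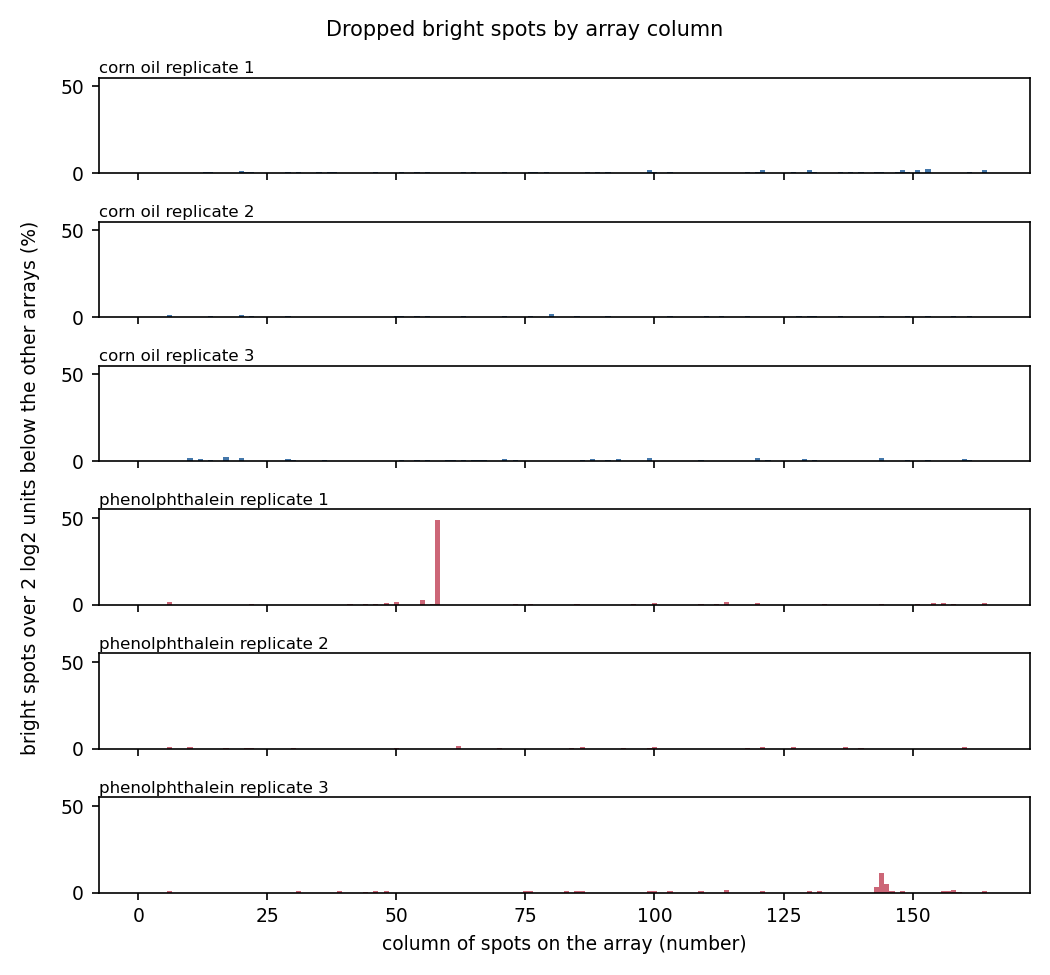
Share of bright spots over 2 log2 units below the other arrays (vertical axis, %) by column of spots (horizontal axis, column number), 1 panel per array. Column 58 of phenolphthalein replicate 1 reaches 49.1% and column 144 of phenolphthalein replicate 3 reaches 11.3%.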

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

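Every test in this part was chosen after the data were seen. Accessions without a match in the RefSeq table were outside the main comparison, and an alternative setting tested them together with the named genes. Tested on their own, with limma and Benjamini-Hochberg adjustment over 17891 accessions, 7 were higher with phenolphthalein than in the corn oil animals, a signal in probes outside the main comparison, and 1 was lower. Some of the 7 carry only a probe name in place of an accession. Whether these probes read genes already in the main comparison was not tested, so the 7 need not be further transcripts. NM_001047923 had a log2 fold change of 4.69 ± 0.29 (SE, limma adjusted p = 0.0269), from -3.34 ± 0.46 to 1.36 ± 0.37 (SD, n = 3 per group), and was higher on 3 of 3 phenolphthalein arrays. NM_001134574 had one of 1.93 ± 0.12 (SE, limma adjusted p = 0.0269). The accession that fell, XM_002724754, was at least 2.88-fold lower with phenolphthalein (limma adjusted p = 0.0269), where it was well above background on 0 of 3 arrays, against 3 of 3 in corn oil. At an unadjusted p under 0.05 there were 2178 accessions, where 895 are expected by chance. These were not named here, and slide and treatment cannot be told apart for them either.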

How the results depend on the processing

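The arrays' slide could not be used as a block, because each slide held 1 group, and that alternative was not run. The 2 added settings, masked columns and accessions without a name included, were chosen after the data were seen, and no cause of a change was tested unless stated. Apart from the fits that leave out 1 array, genes higher (6) kept within 1.5 times except with the replicate block (0) and with accessions without a name included (13). The 2-fold higher count (6) went the same way, at 0 and 13. These block fits use fewer residual degrees of freedom. Over all genes, same-numbered animals did not deviate together (correlations of deviations -0.03, 0.02 and 0.00). The circadian list was otherwise, since its members' median deviation was highest on the third replicate of both groups. It was -0.22, -0.10 and 0.29 on corn oil replicates 1 to 3 and -0.16, -0.21 and 0.315 on phenolphthalein replicates 1 to 3. These medians hide larger, opposite moves, shown by Dbp and Bmal1, chosen after their values were seen. Dbp read 5.92 and 6.17 on the third corn oil and phenolphthalein replicates and 2.43 to 3.79 on the other arrays. Bmal1 read -0.54 and -0.46 there and 0.96 to 1.67 on the other arrays. A pairing by number that touches such genes stays open. With the replicate block, lists higher and lower were 4 and 5, and the female-predominant list passed (adjusted p = 0.0162). The 1 gene lower became 0 with normexp, quantile normalization, no filter, the intensity trend and the replicate block, and 2 with the filter on all 6 arrays. The 2-fold lower count of 0 became 1 with accessions without a name included. Leaving out 1 array, which leaves fewer samples, gave 0 to 6 genes higher, 0 to 0 lower, 0 to 6 higher at 2-fold and 0 to 0 lower at 2-fold. Lists higher (4) became 2 with quantile normalization, 2 with the median shift, 8 with no filter and 0 with camera at an estimated correlation, and 2 to 7 without 1 array. Lists lower (4) became 0 at an estimated correlation and 1 with fry, and 3 to 6 without 1 array. The median shift moved the median of all genes by 0.08 log2 units.

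The calls of CAR and PXR targets and of glucuronidation held in 19 of 20 alternatives and those of interferon response and macrophages in 18 of 20, with medians of 0.43 to 0.65, 0.14 to 0.31, -0.70 to -0.50 and -0.79 to -0.50. The lymphocyte call held in 19 of 20, and those of cholesterol synthesis, glucose and glycogen and PPAR-alpha targets in 13, 10 and 15 of 20. Among lists that had not passed, the male-predominant list passed in 5 of 20, amino acid and cholangiocyte lists in 4 each, acute phase and ER stress in 3 each, female-predominant and stellate lists in 2 each, and AhR targets, cell cycle and immediate early genes in 1 each. With fry, adjusted p was 0.0089 for CAR and PXR targets, 0.0334 for glucuronidation and 0.0477 for lymphocytes, 0.0907 for interferon response and 0.0815 for macrophages. The fry adjusted p was 0.05325 for glucose and glycogen and 0.513 for both cholesterol synthesis and PPAR-alpha targets, so these did not pass either. Adjusted p of Cyp2b1 ran from 0.00282 to 0.167 over 18 alternatives, 12 of them past the threshold, and that of Neurod6 from 0.0235 to 0.292, 6 of them past it. With the mean of a gene's probes, Cyp2b15 had an adjusted p of 0.246.

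Direction reversed only for genes and lists that had not passed. Log2 fold changes were -0.018 for Abcc2 and 0.021 for Retn with normexp, -0.071 for Alb and 0.036 for Retn with quantile normalization, and 0.125 for Cdkn1a with the mean of its probes. Without 1 array they ran from -0.046 to 0.142 for Abcc2, -0.079 to 0.968 for Abcc3, -0.014 to 0.032 for Alb, -0.736 to 0.148 for Fabp4, -0.388 to 0.344 for Nqo1, -0.944 to 0.107 for Per2 and -0.408 to 0.239 for Retn. For lists, camera's direction relative to the other genes turned, at these medians. Bile acid genes had 0.034 with no filter and 0.041 with the replicate block, and the circadian list 0.014 with the median shift, -0.069 with the mean of probes and -0.065 with accessions without a name. Hepatocyte markers had 0.012 with normexp and -0.04 with quantile normalization, which also gave -0.025 for iron and haem, 0.119 for pancreatic acinar and 0.017 for periportal genes. Pancreatic acinar genes had 0.085 with the filter on all 6 arrays. Without 1 array, medians ran from -0.01 to 0.093 for bile acid, -0.15 to 0.095 for circadian, 0.027 to 0.133 for fatty acid, -0.201 to 0.037 for heat shock, -0.014 to 0.082 for hepatocyte, -0.022 to 0.052 for iron and haem, 0.002 to 0.092 for p53, 0.009 to 0.11 for pancreatic acinar and 0.023 to 0.272 for preneoplastic focus genes.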

Other observations

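The tests in this part were chosen after the results they weigh were seen, apart from the list test with an estimated correlation, which was planned. Beside the Cyp2b genes, members of the CAR and PXR list that did not pass over all genes had higher means, here chosen after their values were seen. Cyp2c6v1, a drug-metabolising P450, had a log2 fold change of 0.97 ± 0.13 (SE) and the carboxylesterase Ces2c one of 1.70 ± 0.30. The mean was higher for 20 of the list's 22 members. Over all tested genes, the groups did not overlap for 23.2%, where chance gives 10%.

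Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 7 genes past the threshold and the highest other split 2, and 1 split, the real one, gave as many. For genes changed at least 2-fold the real count was 6 and the highest other 2, again with 1 split as large. For gene lists the real count was 8 and the highest other 11, and 2 splits gave as many. The other splits, which mix the groups, gave 11, 2, 6, 3, 2, 7, 6, 6 and 6 lists with camera's preset correlation. That test thus called lists for mixed groups as well. The 10 splits are too few for a share under 0.05.

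The rise of the Cyp2b genes and Ugt2b1 was set against a shift of bright probes on the phenolphthalein slide. The other 1175 genes in the same range of mean signal had a median log2 fold change of 0.07 with an SD of 0.30, far below 1.84, the smallest of the 6, which argues against it. A slide or handling effect on particular genes stays open, since 0 slides held both groups. For Cyp2b12, its second probe was well above background on 0 treated arrays, so the tested probe may read RNA of another Cyp2b gene, and a second probe that does not work would give the same. An effect of the treatment stays open too, as untested.

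Interferon, macrophage and lymphocyte genes were lower together. If dim probes read lower on the phenolphthalein slide, lists of the same mean signal would shift alike, but 0% of 10000 such random lists had a lower median than interferon response, 0% than macrophage markers and 0.2% than lymphocyte markers, with random medians of 0.03, 0.04 and -0.05. A higher share of hepatocyte RNA would lower all other cell types alike, but the log2 fold changes of 66 markers differed between the 9 lists of other cell types (permutation p = 1e-05, the smallest that 100000 permutations can give, and at most 4e-05 without any 1 array, over genes, which are not independent). The permutation p decides little, since the macrophage list was weighed because it fell and its genes had an estimated correlation of 0.517. Some adipocyte and pancreatic acinar markers were also dim, such as Fabp4 at -3.64 and Cela2a at -4.38 in corn oil. The medians without 1 array argue against such a share as the only cause of the macrophage fall and leave a part in it open. They ran from -0.79 to -0.50 for macrophage markers. For lymphocyte markers, which fell most like them, they ran from -0.51 to -0.33, so these ranges overlap and a shared cause of both stays open. For the others they ran from -0.24 to -0.12 for stellate, -0.35 to -0.06 for erythroid, -0.36 to -0.03 for adipocyte and -0.12 to -0.03 for endothelial markers. They ran from -0.28 to 0.08 for neutrophil, 0.01 to 0.11 for pancreatic acinar and 0.12 to 0.34 for cholangiocyte markers. Fewer or less active immune cells with phenolphthalein and a slide or handling effect both stay open, and 0 lists passed with an estimated correlation.

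The line of dim spots on phenolphthalein replicate 1 may be a defect of the array. Of its 30 spots with a gene name, 13 had another bright probe of the gene elsewhere, and those other probes deviated by 0.009 log2 units in the median (SD 0.19), against -8.09 for the spots on the line. These values argue against lower expression of those 13 genes in that animal. The other 17 spots had no such probe. Yet 57 of 60 bright spots of the column dropped in even rows and 0 of 56 in odd rows. Expression does not follow the row of a spot, so this argues against lower expression for the spots of the line as a set. It was not tested for each of the 17. No other biological explanation was tested.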
